A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

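The samples were 28 arrays of budding yeast, BY4741 per the labels, from WT, kin28as, SPT16-TET, SPT6-TET and SPT16-TET/spt6∆202 cells. Per the labels, cells grew in synthetic complete medium with sulfometuron methyl at 0.65 µM, for 20 min in the protocol text and 30 min in the series design. Per the labels, kin28as cells received 1NA-PP1, dox was used at 10 µg/ml, and 100 ml of culture was crosslinked with 1% formaldehyde for 15 min and sonicated to 300 to 400 bp. ChIP DNA was labelled with Alexa555 and input DNA with Alexa647, per the labels.

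The scanner files hold intensity values that, per the file headers, were background-subtracted, spatially detrended and linearly dye-normalised by Agilent Feature Extraction 11.0.1.1, and also the raw median intensity of each spot and its background. The deposited table holds log2 values of ChIP over input, and neither its header nor the labels state the method, centring or scaling. Each deposited column correlated with the log2 ratio of its own scanner file with an r between 0.894 and 0.997, and its median lay between −0.04 and −0.01. Of 41775 probes that are not controls, 41753 carried a position in build sacCer2 per the file headers, 295 of them mitochondrial. Probes had a median length of 60 bp and a median spacing of 257 bp. The files carry no gene names, and the gene table used here belongs to a later assembly, so no probe was assigned to a gene.

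For each probe the log2 ratio of the processed ChIP and input signals was taken. The median of all probes with a position, mitochondrial ones included, was subtracted for each array. Probes were averaged in bins of 1000 bp by their centre. The number of arrays, 2 per group, limits the precision. Between 99.7% and 99.9% of probes lay well above background, between 0.823% and 31.0% of input spots were saturated, and between 2 and 13065 spots per array were marked as outliers by the scanner software. Replicate arrays correlated across probes with an r between 0.831 (kin28as Spt16-Myc) and 0.982 (SPT16-TET dox Rpb3).

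The groups, the comparisons and the rule for named items were fixed before the data were examined. They named genes, so bins took the place of genes after the files had been read for their units and before any comparison was fitted. Bins were tested with limma 3.58.1 in R 4.3.3, with all groups of an antibody in a single fit, the empirical Bayes trend on, two-sided tests and Benjamini-Hochberg adjustment over the bins of a comparison, at an adjusted p of 0.05. In all, 15 comparisons were made, and the comparison of the Spt16-Myc and Rpb3 changes in kin28as used the 4 groups of both antibodies. Named regions were the 8 highest and 8 lowest runs of adjacent called bins per comparison. Each had at least 3 probes in its strongest bin and lay more than 20000 bp from the outermost probe of its chromosome. In comparisons of 2 groups, both arrays of a group also lay above both of the other. This was not required for differences between changes. The report names some of these, chosen after their values were seen, and those on missing input DNA only as such.

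Classes of bins were ranked on arrays outside the comparison: the highest and lowest by Rpb3, the highest by Spt16-Myc, and the highest and lowest by H3. Subtelomeric bins lay within 20000 bp of the outermost probe. Up to 7 classes per comparison were tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. Runs for the shift of Rpb3 held at least 4 consecutive probes with gaps up to 600 bp, each among the probes with the highest Rpb3, and were oriented where the H3 of their flanks differed by at least 0.5 on the log2 scale. The shift is Rpb3 of the part away from the H3-poor end minus Rpb3 of the part next to it, tested with fry over 6 comparisons. It stands in for the planned difference between gene ends, which could not be computed without gene positions. Correlations expected from a shared control were taken from 100 simulations of unchanged groups. Input DNA was called missing where at least 3 neighbouring probes were low against the other strains, or where the probe lay 3 log2 units or more below its array's median.

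The fits were tested on simulated data, with 200 changed bins per comparison. Changes of 1 on the log2 scale were found in 92% to 100% of bins, and changes of 0.5 in 73% to 96% for differences between 2 groups and in 40% to 56% for differences between changes. Between 3 and 13 unchanged bins were called.

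Alternatives were normexp background correction with an offset of 50 (planned on mean and run on median signals), the deposited values, arrays scaled to the same median absolute deviation, a filter on dim probes, bins with at least 3 probes, medians of probes, fits with only the groups compared, a replicate block, and each array left out in turn. Alternatives chosen after seeing the data were centring on mitochondrial probes, leaving out saturated spots, bins with missing input or 2 doubted Rpb3 arrays (kin28as replicate 2 and SPT16-TET/spt6∆202 without dox replicate 1), an equal slope on all arrays, and reading the ChIP and input channels on their own in the strongest bins of named regions. A slide block gives identical values for comparisons within a slide and cannot be estimated for those across slides. The arrays lay on 8 slides scanned on 5 days. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.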

Results

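The series measured where the FACT subunit Spt16, RNA polymerase II and histone H3 lay along the genome of budding yeast (Saccharomyces cerevisiae). FACT and Spt6 are histone chaperones that act on nucleosomes during transcription. Chromatin was precipitated with antibodies against Myc-tagged Spt16, the polymerase II subunit Rpb3 or H3, and each precipitate was hybridised against input DNA on a tiling array. The 28 arrays formed 14 groups of 2, which the labels call biological replicates: 4 arrays for Spt16-Myc, 14 for Rpb3 and 10 for H3. The strains were wild type (WT), kin28as with its kinase inhibitor 1NA-PP1, SPT16-TET with and without doxycycline (dox), SPT6-TET with dox, and SPT16-TET/spt6∆202 with and without dox. In the TET strains a tetracycline-controlled promoter drove SPT16 or SPT6, so that dox should lower its expression. The arrays did not measure how much Spt16 or Spt6 was left after dox. All cultures received sulfometuron methyl, which induces the transcription factor Gcn4. The number of arrays limits the precision. Values are log2 of ChIP over input relative to the median of the array, averaged over bins of 1000 bp in the coordinates of build sacCer2. Regions are named by position, since the arrays carry no gene names, and a value of a region is that of its strongest bin.

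In WT cells Spt16 followed polymerase II. Across 11479 bins the mean Spt16-Myc level had a Pearson r of 0.880 and a Spearman rho of 0.854 with the mean Rpb3 level, with 2 arrays of each. The bins are neighbours on chromosomes and not independent replicates. The bin from 326001 on chromosome XI was among the highest for both, with an Rpb3 level of 2.09 ± 0.04 (SD, n = 2) and an Spt16 level of 1.92 ± 0.03 (SD, n = 2). On chromosome V from 68001, Rpb3 stood at 2.14 ± 0.05 and Spt16 at 1.77 ± 0.03 (SD, n = 2). The bin from 806001 on chromosome XII had the highest Spt16 level outside bins with missing input DNA, 2.13 ± 0.06 (SD, n = 2). In kin28as cells the relation had an r of 0.794 and a rho of 0.784 over 11177 bins. No correlation between levels was tested across arrays, since a group held 2.

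Kin28 is the kinase of TFIIH that phosphorylates the tail of polymerase II, and the kin28as comparison asks how its inhibition alters polymerase II and Spt16 on genes. Rpb3 fell where WT polymerase II was dense. On chromosome IX from 320001 to 325000 it went from 0.94 in WT to −0.80 in kin28as, a log2 change of −1.73 (SE 0.07, n = 2 per group, adjusted p = 1.23e-07). On chromosome VII from 273001 to 276000 it fell from 1.96 to 0.44, and on chromosome XIV from 351001 to 353000 from 1.52 to −0.28. Rpb3 rose on chromosome XVI from 193001 to 195000, from −0.29 to 1.23 (2.87-fold, SE of the log2 change 0.06, adjusted p = 1.23e-07). It also rose 2.14-fold on chromosome X from 167001 to 169000 and 2.07-fold from 170001 to 174000. In all, 936 of 11162 bins rose and 1273 fell in limma. More bins were called with the deposited values and fewer in a fit of only these groups, with counts in the part on processing. Among the 1116 bins highest for Rpb3 in SPT16-TET cells without dox, 85.3% had a lower Rpb3 value in kin28as and the median log2 change was −0.29 (camera adjusted p = 8.31e-30). That call did not hold with a correlation estimated from the data (adjusted p = 0.217 with an estimated correlation). The lowest 1116 bins rose by a median of 0.12, with 133 called higher and 6 lower. A flatter response of the kin28as arrays gives that pattern too, as their slopes against the other Rpb3 groups were 0.89 and 0.91, and those of WT 1.11 and 1.11. Relative to the other bins, the highest class stood at −0.31 as reported and at −0.26 with arrays scaled to the same spread. The count was 709 without WT replicate 1 and 630 without WT replicate 2, and 9 bins were called when arrays were centred on mitochondrial probes, without the named changes on chromosomes VII and X. The groups were also on different slides and scanned on different days, and strain, slide and day cannot be told apart.

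Spt16-Myc fell with Rpb3 at many of the same places. On chromosome VII from 272001 to 275000 it went from 1.95 ± 0.13 in WT to 0.38 ± 0.08 in kin28as (SD, n = 2), a log2 change of −1.57 (SE 0.11, adjusted p = 0.00517). It fell from 2.06 to 0.80 on chromosome III from 66001 to 69000 and from 1.44 to 0.18 on chromosome V from 264001 to 266000. On chromosome XVI from 194001 to 195000 Spt16-Myc rose 1.78-fold (SE of the log2 change 0.08, n = 2 per group, adjusted p = 0.00604). Of 11480 bins, 420 rose and 1088 fell. In the 1148 bins highest for Rpb3, 92.2% had a lower Spt16-Myc value and the median log2 change was −0.38 (camera adjusted p = 6.91e-53, and adjusted p = 0.034 with an estimated correlation). Both kin28as arrays, with class medians of 0.33 and 0.26, lay below both WT arrays at 0.68 and 0.69. The lowest 1148 bins by Rpb3 rose by a median of 0.13 (adjusted p = 0.0146 with an estimated correlation) and 564 subtelomeric bins rose by 0.08 (adjusted p = 0.0227 with an estimated correlation). Rpb3 and Spt16-Myc both fell in 554 bins against 120 expected of independent lists, and both rose in 144 against 34.3. Across 11142 bins the changes had an r of 0.598. The kin28as arrays also had a smaller spread for Spt16-Myc, with median absolute deviations of 0.40 and 0.37 against 0.44 and 0.43 in WT. A flatter response for both antibodies lowers dense bins and raises sparse ones, which alone gives shared calls and a positive r. The overlap was not recomputed with arrays brought to the same spread, and kin28as and WT lay on different slides for both antibodies. The count of Spt16-Myc bins was 4723 without kin28as replicate 1, 3034 without kin28as replicate 2, 687 without WT replicate 1 and 803 without WT replicate 2. With a replicate block it was 2974, 40.6% of them higher, against 27.9% as reported. Centring on mitochondrial probes moved the median of all bins to 0.52, and 9735 bins were called, 98.6% of them higher. The fall of the class is thus relative to the other bins, at −0.41 as reported and −0.35 with arrays scaled to the same spread.

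Whether Spt16 changed more than polymerase II was tested as the difference between the changes of the antibodies. In limma 0 of 11146 bins passed an adjusted p of 0.05 for it, and 1540 had an unadjusted p under that value. Among the 223 bins highest for Rpb3 the median difference was −0.23, a larger fall in the log2 value of Spt16-Myc than of Rpb3 (camera adjusted p = 9.35e-11). That call did not hold with an estimated correlation (adjusted p = 0.278). In the wider class of 1115 bins the median was −0.093 (camera adjusted p = 0.00367, but adjusted p = 0.299 with an estimated correlation). The antibodies differ in range, so a difference in array response can give such values without Spt16 falling further than polymerase II. Across bins the slope of Spt16-Myc on Rpb3 was 0.68 in WT and 0.56 in kin28as, and the response of single Spt16-Myc arrays was not measured. Without kin28as Rpb3 replicate 1 the count was 988, and without kin28as Rpb3 replicate 2 it was 4. With centring on mitochondrial probes, which moved the median of all bins to 0.39, it was 3312, 99.8% of them higher.

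The SPT16-TET comparison asks what loss of Spt16 does to polymerase II and to histones, with arrays of both conditions on the same slide. Polymerase II fell after dox at places where it had been dense. Rpb3 went from 1.90 to 0.56 on chromosome X from 267001 to 271000, from 1.41 to 0.08 on chromosome IX from 321001 to 325000 and from 2.77 to 1.45 on chromosome XV from 218001 to 220000. The log2 change on chromosome IX was −1.33 (SE 0.08, n = 2 per group, adjusted p = 3.35e-06). Elsewhere it rose: on chromosome V from 323001 to 325000 it went from −0.10 ± 0.12 to 1.16 ± 0.06 (SD, n = 2), 2.39-fold higher (SE of the log2 change 0.12, adjusted p = 5.97e-05). It rose 2.01-fold on chromosome IV from 1445001 to 1447000, 1.94-fold on chromosome II from 95001 to 101000 and 1.91-fold on chromosome X from 522001 to 524000. Of 11162 bins, 1283 rose and 1459 fell. In the 1116 bins highest for Rpb3 in WT cells the median log2 change was −0.25 and 78.7% of values were lower (camera adjusted p = 4.87e-17, but adjusted p = 0.39 with an estimated correlation). The class medians were 0.91 and 0.91 on the dox arrays and 1.16 and 1.18 on those without dox. The lowest 1116 bins rose by a median of 0.090, with 170 called higher and 9 lower. The dox arrays also had a flatter response, with slopes of 1.08 and 1.05 against 1.25 and 1.20, which lowers dense bins too. Relative to the other bins, the highest class stood at −0.26 as reported and at −0.20 with arrays scaled to the same spread. The count of 2742 bins became 1118 with an equal slope on all arrays, 1245 with normexp background correction, 5002 in a fit of only these groups and 4506 without 2 doubted arrays of other groups (kin28as replicate 2 and SPT16-TET/spt6∆202 without dox replicate 1). Leaving out a single array gave 1124 bins without dox replicate 1, 1203 without dox replicate 2, 1476 without the first array lacking dox and 1523 without the second. With centring on mitochondrial probes 3 bins were called, and the named changes on chromosomes IV, IX, X, XV and II lost their call.

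H3 moved at fewer places. On chromosome IV from 1444001 to 1446000 it fell from −0.08 ± 0.13 to −1.37 ± 0.16 (SD, n = 2), a log2 change of −1.29 (SE 0.13, adjusted p = 0.00182), in the same bin where Rpb3 rose most in that region. On chromosome V from 322001 to 324000 it fell from −0.70 to −1.80 (adjusted p = 0.0115), overlapping a region where Rpb3 rose, and on chromosome X from 520001 to 522000 from −0.91 to −1.99 (adjusted p = 0.017), next to such a region. H3 rose 2.55-fold on chromosome VII from 99001 to 103000 (SE of the log2 change 0.09, n = 2 per group, adjusted p = 5.61e-05), where Rpb3 fell. Of 11482 bins, 20 rose and 98 fell. Bins with higher Rpb3 and lower H3 numbered 39 against 11.1 expected of independent lists, and bins with lower Rpb3 and higher H3 numbered 11 against 2.48. The 564 subtelomeric bins gained H3 by a median of 0.07, with 29.3% of values lower (camera adjusted p = 2.84e-05, and adjusted p = 0.0113 with an estimated correlation). The median of the bins highest for Rpb3 was −0.05 (camera adjusted p = 0.00641, but adjusted p = 0.462 with an estimated correlation). The count was 13 without dox replicate 1, 437 without the first array lacking dox and 10 without the second. Without dox replicate 1 or without the second array lacking dox, the bins on chromosomes V and X were no longer called. With normexp background correction 3 bins were called, and the falls named on chromosomes IV, V and X were not among the called ones.

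**Figure D1:**
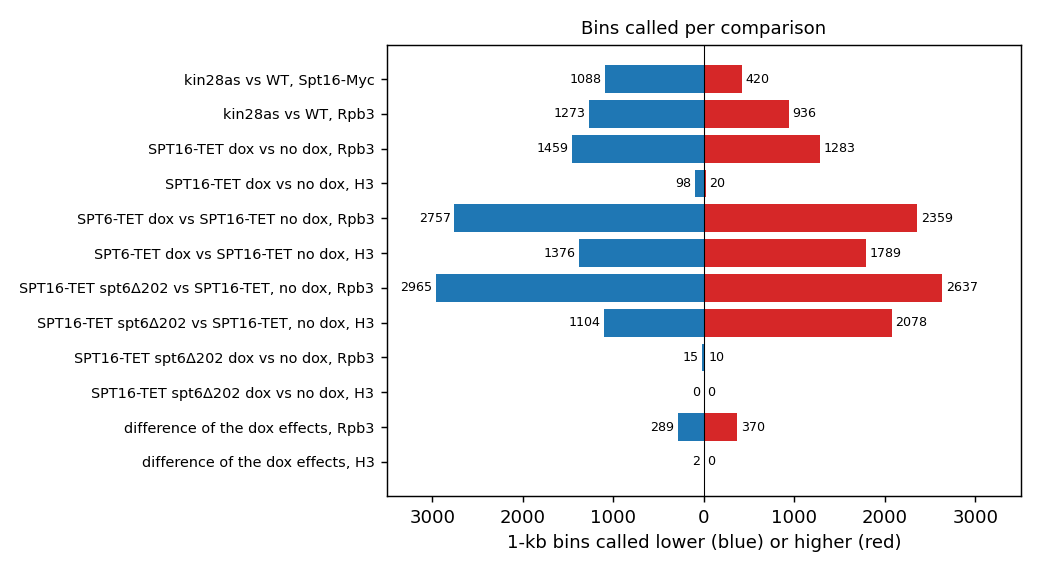
Bars show the number of bins of 1000 bp called higher (to the right) and lower (to the left) in each comparison of Rpb3, H3 or Spt16-Myc at an adjusted p of 0.05 in limma, with 2 arrays per group. The comparisons of SPT6-TET or SPT16-TET/spt6∆202 with SPT16-TET hold the most calls, and dox in SPT16-TET/spt6∆202 gave 25 for Rpb3 and 0 for H3.

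The strongest change in SPT16-TET lay on chromosome VII from 99001 to 103000. There Rpb3 was 2.27 ± 0.19 without dox and 0.21 ± 0.006 with it (SD, n = 2), a 4.16-fold fall (log2 change −2.06, SE 0.12, adjusted p = 3.35e-06). In bin_VII_99 Rpb3 stood at 2.58 ± 0.25 in SPT16-TET without dox and at 0.69 ± 0.02 with it, while the SPT6-TET level was 0.18 and the WT level was 0.16. Part of these differences lay in the denominator. In bin_VII_99 the input of the Rpb3 arrays stood at −0.93 in SPT16-TET without dox, −0.0012 with dox, 0.42 in SPT6-TET and 0.41 in WT. The ChIP signal on its own stood there at 1.71, 0.78, 0.59 and 0.59. In bin_VII_101, the strongest bin, the ChIP signal went from 1.65 without dox to −0.21 with it and the input from −0.69 to −0.52. In bin_VII_99 the Rpb3 level of SPT16-TET/spt6∆202 was 0.81 ± 0.26 without dox and 0.24 with dox, a log2 change of −0.56 that did not pass the test (adjusted p = 0.087). The bins on either side of the named region were chosen after their values were seen.

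**Figure D2:**
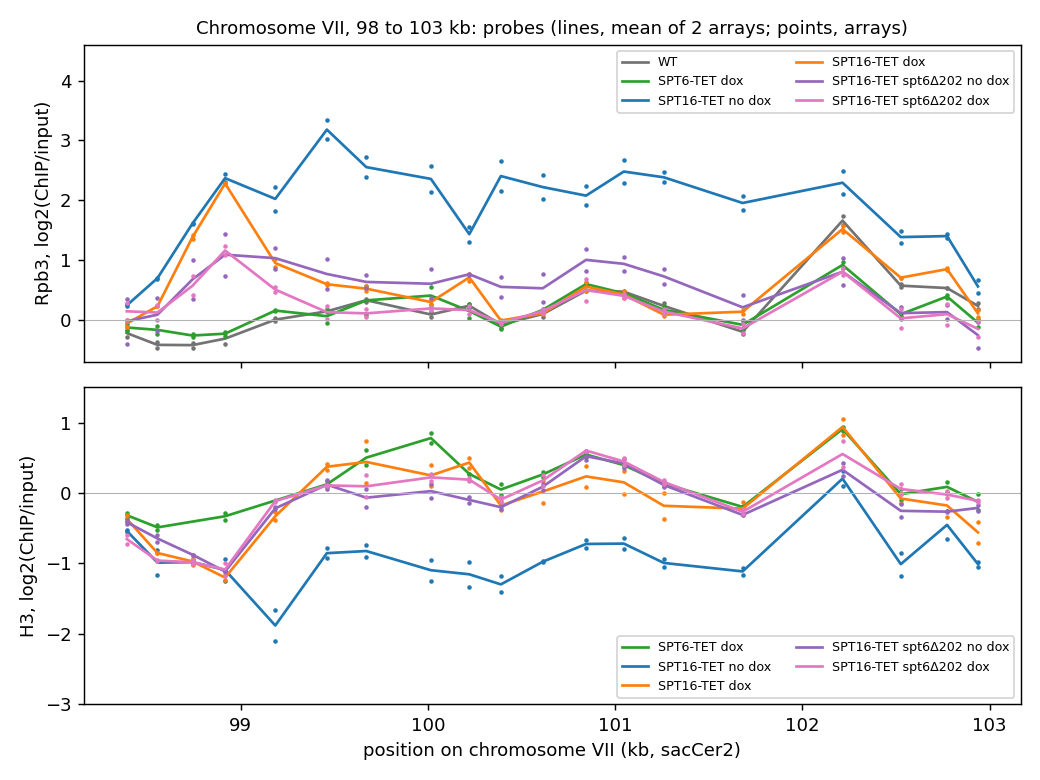
Lines show the mean log2 ChIP/input of Rpb3 and of H3 (n = 2 arrays per group) at each probe along a part of chromosome VII (position in sacCer2, horizontal axis). Rpb3 was high from 99001 to 103000 in SPT16-TET without dox, at 2.27 in the strongest bin, and lower in the same strain with dox.

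Whether polymerase II moved along transcribed stretches was asked in runs of probes with high Rpb3, each oriented by the H3 of its flanks, because promoters are poor in H3. Of 857 runs, 321 could be oriented, with a median length of 1730 bp. Of these, 283 had a value in both parts on all 14 Rpb3 arrays once spots marked as outliers were left out. After dox in SPT16-TET, Rpb3 shifted away from the H3-poor end by a median log2 of 0.11, and 65.4% of runs had a positive shift (fry adjusted p = 0.0121). Array medians were −0.08 and −0.08 with dox and −0.16 and −0.18 without. The shift was 0.11 without either dox array and 0.08 without the second array lacking dox, and was not called in any of those cases. SPT16-TET/spt6∆202 without dox differed from SPT16-TET without dox by 0.11 in the same direction (62.9% positive, fry adjusted p = 0.0026). Where the shift of the control is negative, a flatter response alone gives a positive difference, and both of these comparisons set flatter arrays against steeper ones. With arrays scaled to the same spread the shifts were 0.085 for dox in SPT16-TET (adjusted p = 0.0253) and 0.077 for SPT16-TET/spt6∆202 (adjusted p = 0.0103). With an equal slope on all arrays they were 0.072 (adjusted p = 0.107) and 0.068 (adjusted p = 0.068), and neither was called. The shift did not pass the test for kin28as (−0.05, 322 runs, adjusted p = 0.426), for SPT6-TET against SPT16-TET without dox (0.05, adjusted p = 0.063) or with dox (−0.05, adjusted p = 0.177), or for dox in SPT16-TET/spt6∆202 (0.04, adjusted p = 0.177). The SPT6-TET shift against SPT16-TET without dox was called without SPT6-TET replicate 1, at 0.06, and was −0.01 without replicate 2. That against SPT16-TET with dox was called without SPT6-TET replicate 2, at −0.06, and with normexp background correction, at −0.26 (adjusted p = 4.39e-05). Runs from fewer probes, those highest for Rpb3, gave calls for kin28as at −0.13 and for SPT6-TET against SPT16-TET without dox at 0.090 (both adjusted p = 0.0181). The latter was also called in runs of at least 6 probes, at 0.055 (adjusted p = 0.0326).

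**Figure D3:**
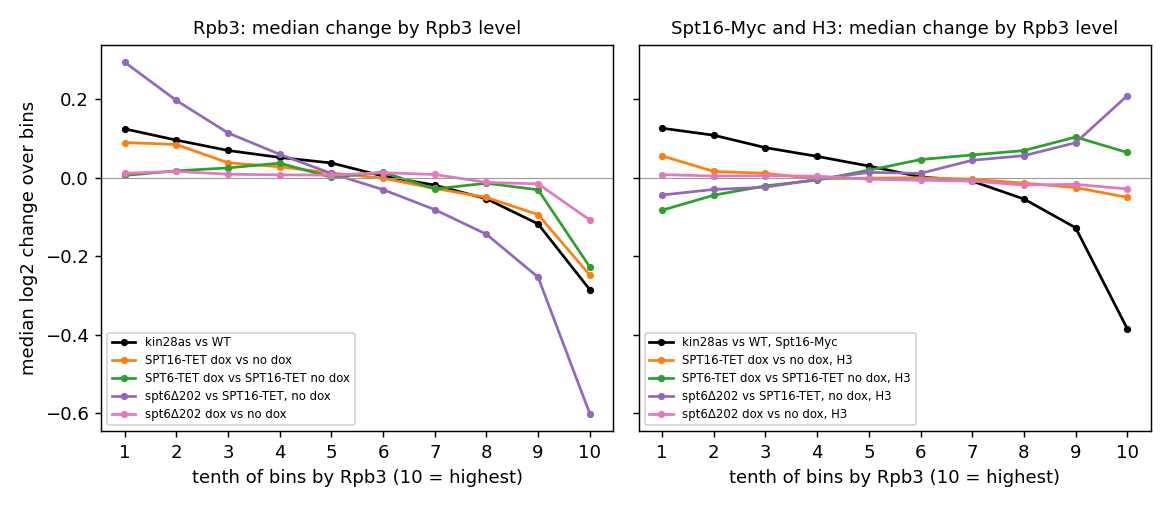
Median log2 change (vertical axis) of bins ranked into 10 classes by Rpb3 level on arrays outside the comparison (horizontal axis, lowest to highest), with 1 line per comparison. Rpb3 in the highest class was lower by 0.25 after dox in SPT16-TET and by 0.60 in SPT16-TET/spt6∆202 without dox against SPT16-TET without dox.

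The effect of Spt6 loss was asked in SPT6-TET with dox, which had no arrays lacking dox and was set against SPT16-TET without dox. Dox itself and the gene under the tetracycline-controlled promoter thus differed as well. Rpb3 was lower on chromosome III from 65001 to 71000, at 0.98 against 2.25 (log2 difference −1.28, SE 0.09, n = 2 per group, adjusted p = 1.42e-05), and on chromosome X from 470001 to 473000, 2.18-fold. Most of the difference on chromosome III lay in the input, which differed by 1.02, against −0.33 for the ChIP signal. It was higher on chromosome X from 570001 to 572000, at 0.74 against −0.36 (2.15-fold, SE of the log2 difference 0.09, adjusted p = 2.22e-05), and on chromosome XIII from 841001 to 850000, at 0.39 against −0.59. H3 was higher on chromosome XV from 908001 to 909000, at −0.31 against −1.22 (1.87-fold, SE 0.09, adjusted p = 0.000222), and on chromosome XI from 143001 to 145000, 1.75-fold. H3 was lower on chromosome VIII from 451001 to 452000, at −1.38 against −0.56 (adjusted p = 0.000562), with differences of −0.47 in the ChIP signal and 0.44 in the input. Rpb3 was higher in 2359 bins and lower in 2757 of 11162, and H3 was higher in 1789 and lower in 1376 of 11482. Rpb3 and H3 were both higher in 779 bins against 364 expected of independent lists, and both lower in 772 against 334. Both differences also followed the brightness of the input across probes, with an r of −0.35 for Rpb3 and −0.43 for H3. Such a common trend alone makes the lists overlap, so the overlap does not tell whether Rpb3 and H3 moved together. The 1116 bins highest for H3 had a median Rpb3 difference of 0.29 (camera adjusted p = 1.34e-20, but adjusted p = 0.207 with an estimated correlation), and the 1116 highest for Rpb3 one of −0.23 (adjusted p = 4.72e-07, but 0.533 with an estimated correlation). The Rpb3 count was 3378 without the second SPT16-TET array lacking dox. The H3 count was 900 without SPT6-TET replicate 1, 1296 without SPT6-TET replicate 2 and 1322 without the second SPT16-TET array lacking dox. With normexp background correction H3 was higher in 31.8% of called bins, against 56.5% as reported. Without saturated input spots 67.6% of called Rpb3 bins and 87.1% of called H3 bins were higher, so the balance between rises and falls depended on the processing.

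Set against SPT16-TET with dox, SPT6-TET with dox was meant to compare the loss of either chaperone. Rpb3 was lower in SPT6-TET on chromosome IV from 1320001 to 1322000, at 0.21 against 1.59 (log2 difference −1.38, SE 0.08, n = 2 per group, adjusted p = 4.67e-06), and on chromosome VII from 167001 to 172000, at −0.64 against 0.59. It was higher on chromosome XIII from 845001 to 850000, at 0.39 against −0.81 (2.29-fold, adjusted p = 4.67e-06), and on chromosome IV from 1365001 to 1368000, where in the strongest bin the input differed by −0.60 and the ChIP signal by 0.51. H3 was higher on chromosome XI from 143001 to 148000, 1.81-fold (SE of the log2 difference 0.08, adjusted p = 0.000174). Rpb3 was higher in 2706 bins and lower in 2850, and H3 was higher in 1912 and lower in 1360. H3 of the 1148 bins highest for Rpb3 was higher by a median of 0.13 (camera adjusted p = 0.000125, but adjusted p = 0.222 with an estimated correlation). The Rpb3 count was 3647 without the second SPT16-TET dox array. The H3 count was 1052 without SPT6-TET replicate 1, 1532 without SPT6-TET replicate 2 and 1151 without the first SPT16-TET dox array. Without saturated input spots 73.8% of called Rpb3 bins and 87.1% of called H3 bins were higher. With normexp background correction 36.8% of 5614 H3 bins were higher, against 58.4% as reported.

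The effect of the spt6∆202 allele was asked without dox, in SPT16-TET/spt6∆202 against SPT16-TET. Polymerase II was lower at dense places: Rpb3 stood at 0.38 ± 0.15 against 2.25 ± 0.10 (SD, n = 2) on chromosome III from 64001 to 73000, a log2 difference of −1.87 (SE 0.09, adjusted p = 4.82e-07). It stood at 0.31 against 2.02 on chromosome I from 71001 to 74000 and at 0.10 against 1.76 on chromosome VII from 21001 to 29000. Part of these differences lay in the input, which differed by 0.72, 0.74 and 0.47 on chromosomes III, I and VII. The ChIP signal differed there by −1.13, −0.95 and −1.17. Rpb3 was higher on chromosome XV from 228001 to 231000, at 0.39 against −0.83 (2.33-fold, adjusted p = 1.76e-06). H3 was higher 2.26-fold on chromosome XV from 908001 to 909000 (SE of the log2 difference 0.09, adjusted p = 7.1e-05) and 2.48-fold on chromosome XI from 355001 to 356000. Rpb3 was higher in 2637 and lower in 2965 of 11162 bins, and H3 was higher in 2078 and lower in 1104 of 11482. In the 1116 bins highest for Rpb3, 88.7% of Rpb3 values were lower, with a median of −0.60 (camera adjusted p = 2.19e-33, but adjusted p = 0.106 with an estimated correlation). The 1116 bins lowest for Rpb3 moved the other way, by a median of 0.29, with 565 called higher and 12 lower. Arrays with a flatter response give that pattern too: the slope against the other Rpb3 groups was 0.60 and 0.84 in SPT16-TET/spt6∆202 and 1.25 and 1.20 in SPT16-TET. Relative to the other bins, the highest class stood at −0.64 as reported and at −0.32 with arrays scaled to the same spread. H3 of the 1148 bins highest for Rpb3 was higher by a median of 0.21 (camera adjusted p = 1.48e-12, but adjusted p = 0.124 with an estimated correlation). The H3 slopes were also lower, at 0.74 and 0.86 against 1.07 and 0.91 in SPT16-TET. A flatter response raises bins poor in H3, and the class medians on the SPT16-TET arrays were −0.27 and −0.28. The H3 difference also followed the brightness of the input across probes, with an r of −0.48. The H3 count was 688 without SPT16-TET/spt6∆202 replicate 1, 1010 without its replicate 2 and 953 without the second SPT16-TET array. With normexp background correction 371 H3 bins were called, 18.1% of them higher, and both H3 rises named here lost their call.

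These comparisons between strains crossed slides and scan days, and strain, slide and day cannot be told apart in them. Between SPT6-TET with dox and SPT16-TET without dox, an effect of dox itself cannot be told apart from the strain either. As a gauge, WT and SPT16-TET without dox, both undepleted and on different slides, differed in Rpb3 at 2616 of 11162 bins. Centring on mitochondrial probes left 25 Rpb3 and 86 H3 bins for SPT6-TET against SPT16-TET without dox and 45 and 93 against SPT16-TET with dox. It left 965 and 1024 for SPT16-TET/spt6∆202, with 1.04% and 5.08% of them higher. The comparisons with SPT16-TET without dox also shared that control, which alone gives correlated differences. For Rpb3, dox in SPT16-TET and SPT6-TET had an observed r of 0.278 against 0.502 in simulated data with unchanged groups, a covariance difference of 0.0178. For SPT6-TET and SPT16-TET/spt6∆202 the observed r was 0.674 against 0.50 simulated, a covariance difference of 0.0836. For dox in SPT16-TET and SPT16-TET/spt6∆202 without dox the values were 0.571, 0.502 and 0.0519. For H3, SPT6-TET and SPT16-TET/spt6∆202 had an observed r of 0.588 against 0.50 simulated, a covariance difference of 0.0311. The other H3 pairs lay below the simulated r. Dox in SPT16-TET had an r of 0.280 with SPT6-TET, with a covariance difference of 0.00613, and of 0.0805 with SPT16-TET/spt6∆202, with a covariance difference of −0.00128. The simulated data carry the noise of the shared arrays but no departure of that control from all other groups, which also raises the covariance.

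Whether loss of Spt16 acts on top of the spt6∆202 allele was asked with dox in SPT16-TET/spt6∆202, again within a slide. Rpb3 fell on chromosome XV from 219001 to 220000, from 1.13 ± 0.11 to 0.28 ± 0.08 (SD, n = 2), a log2 change of −0.85 (SE 0.12, adjusted p = 0.0235). It rose on chromosome X from 194001 to 195000, from −0.02 to 0.56 (SE 0.06, adjusted p = 0.0126). In limma 10 of 11162 Rpb3 bins rose and 15 fell, and 1589 had an unadjusted p under 0.05. Of the bins that rose, 9 also rose after dox in SPT16-TET against 1.15 expected of independent lists, and of those that fell, 12 also fell there against 1.96. For H3, 0 of 11482 bins passed in limma and 674 had an unadjusted p under 0.05. In the 1116 bins highest for Rpb3 the median Rpb3 change was −0.11 (camera adjusted p = 3.77e-12, but adjusted p = 0.296 with an estimated correlation). Set against the other bins, that class stood at −0.20 without the first array lacking dox and at −0.02, not called, without the second. The Rpb3 count was 2 without either dox array, 87 without the first array lacking dox and 255 without the second. Both bins named lost their call without dox replicate 1, and with normexp background correction 0 bins were called. The count was higher in other settings: 148 with the deposited values, 481 with arrays scaled to the same spread and 1189 with an equal slope on all arrays.

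The difference between the dox effects of the strains was tested directly. On chromosome XII from 729001 to 730000 the Rpb3 change was more positive in SPT16-TET/spt6∆202 by 1.32 on the log2 scale (SE 0.11, n = 2 per group, adjusted p = 0.000399), and on chromosome II from 105001 to 110000 by 1.23 (adjusted p = 0.000399). On chromosome V from 323001 to 325000 the difference was −1.26 (SE 0.17, adjusted p = 0.00416), where Rpb3 had risen in SPT16-TET, and it was −1.14 on chromosome IV from 1445001 to 1447000. In all, 370 bins had a more positive and 289 a more negative Rpb3 change in SPT16-TET/spt6∆202. Fewer bins were called with arrays scaled to the same spread and with an equal slope on all arrays. More were called with the deposited values and without both doubted arrays, with counts in the part on processing. For H3 2 bins differed, both on chromosome VII from 99001 to 101000, with a difference of −1.26 (SE 0.13, adjusted p = 0.00441), and 882 had an unadjusted p under 0.05 in limma. Subtelomeric H3, which rose by 0.07 in SPT16-TET, had a median change of −0.004 in SPT16-TET/spt6∆202, and the difference of −0.08 passed the test (camera adjusted p = 7.03e-05, and adjusted p = 0.0136 with an estimated correlation). The Rpb3 count was 206 without the second dox array of SPT16-TET/spt6∆202, 1177 without its second array lacking dox, 178 and 251 without the first or the second SPT16-TET array lacking dox, and 121 and 97 without its first or second dox array. The H3 count was 45 without the first SPT16-TET array lacking dox and 0 without the second SPT16-TET/spt6∆202 array lacking dox. Both H3 bins also lost their call with normexp background correction, with arrays scaled to the same spread, with medians of probes and with centring on mitochondrial probes. With centring on mitochondrial probes 0 Rpb3 bins differed, and with normexp background correction 113 did, while the bins named on chromosomes IV and V were not called.

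Rpb3 changed in the same direction at some of the same places after dox in SPT16-TET and in kin28as. Rpb3 fell in both in 546 bins against 166 expected of independent lists and rose in both in 212 against 108, and across 11162 bins the changes had an r of 0.378. The region on chromosome IX near 321001 fell in both, by 1.73 in kin28as and by 1.33 after dox in SPT16-TET on the log2 scale (n = 2 per group). No arrays were shared between these comparisons, but both set flatter arrays against steeper ones. The slopes were 0.89 and 0.91 in kin28as against 1.11 and 1.11 in WT. They were 1.08 and 1.05 with dox against 1.25 and 1.20 without it. A flatter response lowers dense bins and raises sparse ones in both comparisons, which alone gives shared calls and a positive r. The overlap was not recomputed with arrays brought to the same spread or slope.

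The input channel showed stretches where DNA was missing, and the ratio there has no usable denominator. In kin28as the input was low at 16 probes on chromosome II from 469857 to 473946, by a mean log2 of −6.19 against the other strains, and at 9 probes on chromosome XV from 564547 to 566673, by −6.39. The highest apparent rises of kin28as lay there: log2 changes of 2.88 (Rpb3) and 2.53 (Spt16-Myc) on chromosome XV from 564001 to 567000 and of 1.73 and 1.47 on chromosome II from 470001 to 474000. In WT the input was missing at 4 probes on chromosome V from 116139 to 116887, and in SPT16-TET/spt6∆202 at 4 probes on chromosome VII from 723798 to 724584, where Rpb3 appeared higher by 2.03. These stretches were not counted among the biological changes named above, though their bins are in the counts. Among the strongest bins of the 176 regions examined, the input difference moved the ratio in the direction of its change by more than the ChIP difference did in 37. These numbered 0 of 16 for dox in SPT16-TET in Rpb3 and in H3, and 8 of 16 for H3 of SPT6-TET against SPT16-TET with dox. The WT bin from 91001 on chromosome III, the highest for Rpb3 at 2.69, lay in DNA missing from the input of all strains.

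**Figure D4:**
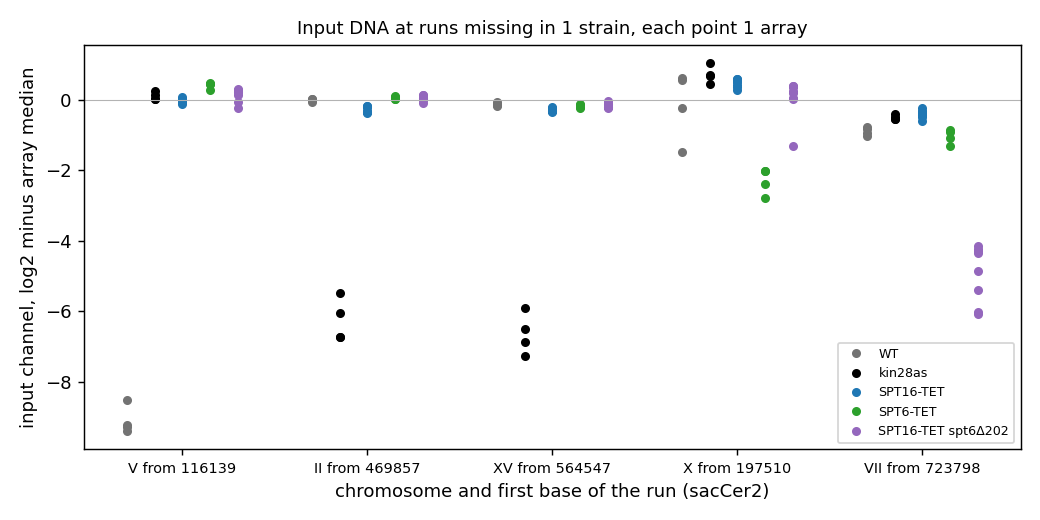
Points show each array's mean log2 input signal relative to its median (vertical axis) over each run of probes where the input of 1 strain lay below that of the others (horizontal axis), with arrays marked by strain. The kin28as arrays lie apart from the rest on chromosomes II and XV, with mean differences of −6.19 and −6.39.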

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

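The tests with the same slope on all arrays, of a single array as the cause, between the undepleted strains and of the ChIP signal at missing input were chosen after the result they bear on had been seen.

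Dox changed Rpb3 in 25 bins of SPT16-TET/spt6∆202 and in 2742 of SPT16-TET, and a test of the difference between the dox effects of these strains passed in 659 bins. A flatter response of the SPT16-TET/spt6∆202 arrays may hide changes, since with the same slope on all arrays 1189 bins were called in that strain and 1118 in SPT16-TET. Against a linear difference in slope as the whole cause, 201 of the 659 bins were called in the same direction as reported, with arrays scaled to the same spread and with the same slope. The Rpb3 array with the highest mitochondrial level, SPT16-TET/spt6∆202 without dox replicate 1, is not the whole cause either, as 87 bins were called for dox in that strain without it. A smaller effect of Spt16 loss in cells that carry spt6∆202 stays open, untested beyond these values. How far dox lowered Spt16 in either strain was not measured by the arrays.

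Rpb3 differed between SPT6-TET and SPT16-TET without dox in 5116 bins and H3 in 3165, between arrays on different slides. After each array's median per class of input brightness had been removed, 4297 Rpb3 and 2049 H3 bins were called. Calls of that number thus arose without a median trend with brightness. Whether they are the bins reported, in the same direction, was not compared, and the removal raised the count in other comparisons. How much of either difference follows brightness could not be decided, because Rpb3 or H3 and input brightness may vary together along the genome. A slide or scan day effect of another kind cannot be told apart from the strain, and 2616 of 11162 Rpb3 bins differed between the undepleted strains WT and SPT16-TET on different slides. Dox, which only SPT6-TET received in this comparison, cannot be told apart from the strain either. A loss of Spt6 function, which the design names, stays open beside these.

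The highest apparent rises of Rpb3 and Spt16-Myc in kin28as lay where the kin28as input signal was missing, a signal in a channel that no comparison used on its own. The input lay below that of the other strains by a mean log2 of −6.19 on chromosome II from 469857 to 473946 and of −6.39 on chromosome XV from 564547 to 566673. A candidate explanation is a ratio raised by the missing denominator: the Rpb3 ChIP signal itself was lower in kin28as than in WT, by −3.81 on chromosome XV and −4.63 on chromosome II. With normexp background correction the Rpb3 changes turned to −0.81 and −2.71. A gain of polymerase II there is argued against by those lower ChIP signals, and the reason for the missing DNA was not tested.

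The dox effect on H3 differed between the strains in 2 bins, both on chromosome VII from 99001 to 101000, which lost their call in some other settings given in the part on processing. The subtelomeric H3 change differed between the strains by a median log2 of −0.081, which was not recomputed with single arrays left out. Input signal was missing in WT on chromosome V from 116139 to 116887, with a mean difference of −9.20 from the other strains over 4 probes. In SPT6-TET it was lower on chromosome X from 197510 to 204147, by −2.51 over 3 probes, and arrays of other strains reached −1.47 there. In SPT16-TET/spt6∆202 it was lower on chromosome VII from 723798 to 724584, by −4.21 over 4 probes.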

How the results depend on the processing

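Centring on mitochondrial probes, the separate reading of ChIP and input, leaving out saturated input spots, bins with missing input or both doubted Rpb3 arrays, an equal slope on all arrays and the stricter choices of runs were chosen after seeing the data. Results were recomputed with a single choice changed, though not every result in every setting. Both doubted arrays were left out only for Rpb3, and an equal slope was set only for dox effects and shifts along runs. Runs were not recomputed with every setting. Classes of bins were recomputed only with an estimated correlation, with arrays scaled to the same spread and with centring on mitochondrial probes. Among classes, single arrays were left out only for the Rpb3-rich one. The subtelomeric H3 results thus have no such check, nor one with normexp background correction. Counts, shifts along runs, values of the Rpb3-rich class and WT correlations that moved in these settings are listed. Those not listed kept their direction and their side of the threshold, or a count within 1.5 times the reported one. Removing each array's median per class of input brightness moved counts further. H3 went from 118 to 304 for dox in SPT16-TET and from 3272 to 2149 for SPT6-TET against SPT16-TET with dox. Rpb3 went from 25 to 68 for dox in SPT16-TET/spt6∆202. The cause of a shift was not tested unless stated. Of 193 values of named regions, 186 kept their call with the deposited values, 179 with arrays scaled to the same spread, 120 with normexp background correction (16 reversed, 57 lost it) and 186 with a replicate block. Centring on mitochondrial probes kept 104 of 193, with 5 reversed. Leaving out an array kept 728 of 840, with 0 reversed and 112 weaker. The mitochondrial centring rests on 295 probes, whose level differed between replicates with an SD of up to 0.65 (SPT16-TET/spt6∆202 Rpb3 without dox). For Rpb3 and H3 replicates share only a number, since residuals of group pairs correlated in either direction, with an r of −0.69 to 0.58 for Rpb3 and −0.36 to 0.40 for H3. For Spt16-Myc there was 1 such pair, with an r of 0.348, which leaves the question open for that antibody. Of probes, 99.7% or more were marked as well above background, while saturation reached 31.0% of input spots. That mark does not show that values are insensitive to background treatment, since 57 of 193 lost their call with normexp background correction. A slide block gives identical values within a slide and cannot be estimated across slides.

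With normexp background correction the counts were 1245 for Rpb3 and 3 for H3 (66.7% higher) after dox in SPT16-TET. They were 4781 (31.8% higher) and 5614 (36.8% higher) for SPT6-TET H3 against SPT16-TET without and with dox, where the median of all bins shifted to −0.11. They were 371 (18.1% higher) for SPT16-TET/spt6∆202 H3 without dox, 0 for its dox effect on Rpb3, 113 for the difference between the dox effects on Rpb3 and 0 for that on H3. The shift along runs for SPT6-TET against SPT16-TET with dox became −0.26 (adjusted p = 4.39e-05), and the WT correlation of Spt16-Myc with Rpb3 was 0.838. Reversed values were, for kin28as Spt16-Myc, −0.73 on chromosome XV from 565001, −1.99 on II from 473001, −0.034 on III from 91001 and 2.34 on V from 116001, and for kin28as Rpb3 −0.81 on XV from 565001 and −2.71 on II from 472001. For SPT6-TET against SPT16-TET without dox they were 0.081 on VII from 481001 and 1.15 on VII from 271001 for Rpb3, and 0.91 on I from 191001 and 0.39 on VI from 225001 for H3. Against SPT16-TET with dox they were 0.82 on VII from 271001 for Rpb3, and 0.99 on I from 191001, 0.43 on VI from 225001, 1.01 on XV from 480001 and 0.94 on V from 474001 for H3. For SPT16-TET/spt6∆202 Rpb3 the value on VII from 724001 was −0.26.

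With centring on mitochondrial probes the counts were 9735 for kin28as Spt16-Myc (98.6% higher, median of all bins 0.52), 3312 for Spt16-Myc minus Rpb3 in kin28as (99.8% higher, median 0.39), 9 for kin28as Rpb3 (77.8% higher, median of all bins 0.12), 3 for Rpb3 (33.3% higher, median 0.31) and 16 for H3 (43.8% higher) after dox in SPT16-TET. For SPT6-TET they were 25 for Rpb3 (median 0.24) and 86 for H3 (median 0.10) against SPT16-TET without dox, and 45 (8.89% higher) and 93 (median 0.11) against SPT16-TET with dox. For SPT16-TET/spt6∆202 without dox they were 965 for Rpb3 (1.04% higher, median −0.35) and 1024 for H3 (5.08% higher, median −0.33). For its dox effect they were 0 for Rpb3 (median 0.58) and 1 for H3 (median 0.10), and for the difference between dox effects 0 for Rpb3 (median 0.28) and 4 for H3 (median 0.11, 100% higher). The Rpb3-rich class then passed for that H3 difference, at 0.016 (adjusted p = 0.00934). Dox values of SPT16-TET/spt6∆202 Rpb3 reversed to 0.016 on VIII from 451001, 0.045 on IX from 323001, 0.070 on XII from 1040001, 0.081 on V from 449001 and 0.13 on IV from 484001.

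Counts with the deposited values were 3776 for kin28as Rpb3, 148 for dox in SPT16-TET/spt6∆202 Rpb3, 1077 for the dox difference in Rpb3 and 3 for Spt16-Myc minus Rpb3 in kin28as. With arrays scaled to the same spread they were 481 for dox in SPT16-TET/spt6∆202 Rpb3 and 344 and 0 for the dox difference in Rpb3 and H3, and the H3 of the Rpb3-rich class passed for SPT6-TET against SPT16-TET without dox (0.066) and for dox in SPT16-TET/spt6∆202 (−0.030). Medians of probes gave 53 for SPT16-TET dox H3, 9 for dox in SPT16-TET/spt6∆202 Rpb3 and 0 for the dox difference in H3. Fits with only the groups compared, which hold fewer arrays, gave 531 for kin28as Rpb3 (23.7% higher), 5002 for Rpb3 and 26 for H3 (30.8% higher) after dox in SPT16-TET, 1900 for SPT6-TET H3 and 2041 for SPT16-TET/spt6∆202 H3 against SPT16-TET without dox, and 26.3% higher of 19 for dox in SPT16-TET/spt6∆202 Rpb3. A replicate block gave 2974 for kin28as Spt16-Myc (40.6% higher), 77 for SPT16-TET dox H3 and 16 for dox in SPT16-TET/spt6∆202 Rpb3. Without saturated spots 54 bins were called for SPT16-TET dox H3, and the share of higher bins rose to 67.6% for Rpb3 and 87.1% for H3 of SPT6-TET against SPT16-TET without dox, to 73.8% and 87.1% against it with dox, to 88.4% for SPT16-TET/spt6∆202 H3, to 51.4% for its dox effect on Rpb3 and to 69.2% for the dox difference in Rpb3. Without bins of missing input 80 were called for dox in SPT16-TET/spt6∆202 Rpb3. Without both doubted arrays the Rpb3 counts were 4506 for dox in SPT16-TET, 406 for dox in SPT16-TET/spt6∆202 and 1713 for the dox difference. With an equal slope on all arrays they were 1118, 1189 (51.2% higher) and 257, and 40 for SPT16-TET dox H3.

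With an equal slope on all arrays the shift along runs lost its call for dox in SPT16-TET (0.072) and for SPT16-TET/spt6∆202 without dox (0.068). Runs from the probes highest for Rpb3 passed for kin28as (−0.13) and SPT6-TET against SPT16-TET without dox (0.090), and the latter also with at least 6 probes (0.055). With an estimated correlation the Rpb3-rich class, set against the other bins, lost its call at unchanged values: −0.31 for kin28as Rpb3, −0.26 and −0.055 for Rpb3 and H3 after dox in SPT16-TET, −0.23 for SPT6-TET Rpb3 against SPT16-TET without dox, 0.11 for SPT6-TET H3 against SPT16-TET with dox, −0.64 and 0.20 for SPT16-TET/spt6∆202 Rpb3 and H3, −0.11 for its dox effect on Rpb3, 0.14 for the dox difference in Rpb3 and −0.091 for Spt16-Myc minus Rpb3 in kin28as. The WT correlation was 0.860 for Rpb3 array 1 with Spt16-Myc array 1 and 0.851 for Rpb3 array 2 with Spt16-Myc array 1.

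Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 687 to 4723 bins for kin28as Spt16-Myc, 630 to 3025 for kin28as Rpb3, 1124 to 1523 for Rpb3 and 10 to 437 for H3 after dox in SPT16-TET. It gave 3378 to 4035 for Rpb3 and 900 to 4033 for H3 of SPT6-TET against SPT16-TET without dox, and 3647 to 4650 and 1052 to 3342 against it with dox. It gave 4109 to 5487 and 688 to 4350 for SPT16-TET/spt6∆202 without dox, 2 to 255 for its dox effect on Rpb3 and 0 on H3 in limma (674 at an unadjusted p under 0.05 with all arrays), 97 to 1177 and 0 to 45 for the dox differences in Rpb3 and H3, and 0 to 988 for Spt16-Myc minus Rpb3 in kin28as. The shift along runs ranged from −0.07 to −0.01 for kin28as, 0.075 to 0.13 for dox in SPT16-TET, −0.0080 to 0.059 for SPT6-TET against SPT16-TET without dox, −0.059 to −0.0026 against it with dox, 0.08 to 0.16 for SPT16-TET/spt6∆202 without dox and 0.03 to 0.06 for its dox effect. The Rpb3-rich class ranged from −0.44 to −0.39 for Spt16-Myc, −0.34 to −0.29 for Rpb3 and −0.12 to −0.066 for their difference in kin28as. It ranged from −0.27 to −0.25 for Rpb3 and −0.063 to −0.037 for H3 after dox in SPT16-TET. For SPT6-TET it ranged from −0.28 to −0.17 and 0.041 to 0.057 against SPT16-TET without dox, and from 0.0063 to 0.12 and 0.10 to 0.12 against it with dox. For SPT16-TET/spt6∆202 it ranged from −0.72 to −0.54 and 0.16 to 0.23 without dox, −0.20 to −0.015 and −0.058 to 0.010 for the dox effect, and 0.041 to 0.24 and −0.0099 to 0.043 for the dox differences.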

Other observations

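The comparison of H3 with Rpb3 between strains and the tests on the 2 stretches of chromosome VII as genes were chosen after the result they bear on had been seen.

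The relation of H3 to polymerase II across bins was compared between strains. In SPT16-TET cells the Rpb3 and H3 levels of bins had an r of −0.20 without dox and −0.21 with dox, in SPT6-TET with dox 0.05, and in SPT16-TET/spt6∆202 0.21 without dox and 0.22 with dox (2 arrays per group, bins not independent). The bins highest for Rpb3 had H3 class medians of −0.27 and −0.28 on the SPT16-TET arrays without dox and of −0.04 and −0.10 on those of SPT16-TET/spt6∆202. Changes of Rpb3 and H3 had an r of −0.30 after dox in SPT16-TET and of 0.49 between SPT6-TET and SPT16-TET without dox. These strains lay on different slides, and no difference between the correlations was tested. H3 differences between slides also followed the brightness of the input, with an r of −0.48 for SPT16-TET/spt6∆202 and −0.43 for SPT6-TET against SPT16-TET without dox, so a slide effect cannot be told apart from the strain here.

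In SPT6-TET with dox, Rpb3 stood at 1.09 ± 0.01 (SD, n = 2) in bin_VII_720 and at 0.26 in SPT16-TET without dox, a log2 difference of 0.83 (adjusted p = 4.7e-05). In bin_VII_722 the difference was −0.47 (adjusted p = 0.000627). These bins were chosen after their values were seen, among those near the run from 723798 treated below. Whether either difference belongs to SPT6, the gene that dox should lower in this strain, was not tested. Input DNA was low in all strains at 6 runs of probes, on chromosome I from 190562, chromosome III from 91014 and from 148731, chromosome XII from 424083 and from 732479, and chromosome XV from 480064.

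The interval on chromosome VII from 99001 to 103000, where Rpb3 fell most after dox in SPT16-TET, may be the SPT16 gene under its tetracycline-controlled promoter, since the locus tag YGL207W places SPT16 on the left arm of that chromosome. If so, Rpb3 should be higher without dox in both strains with SPT16-TET than in strains with the native promoter. In the bin from 99001 the lowest of their 4 arrays without dox had a level of 0.63, and the highest array of WT, kin28as and SPT6-TET had 0.29. In the bins from 100001 and from 101001 these values were 0.52 and 0.30, and 0.47 and 0.35. In the bin from 102001 the lowest array was at 0.030 and the highest of the others at 0.75, so the prediction failed there. Both SPT16-TET arrays without dox lay above the others, at 1.35 and 1.46, and only SPT16-TET/spt6∆202 arrays broke the order. In the bins highest for Rpb3 that strain was lower than SPT16-TET in general, with a median log2 difference of −0.60. The prediction, which covered all 4 arrays, thus stands as failed in the bin from 102001. Whether the lower Rpb3 of SPT16-TET/spt6∆202 accounts for that was not tested. In the ChIP signal without the input, the order broke in each of the 4 bins, with 0.63 against 0.78 in the bin from 99001. Whether the first 3 bins are under the tetracycline-controlled promoter could not be decided, since their order in the ratio rests in part on the input. The position was not compared with an annotation of the same build.

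The run on chromosome VII from 723798 to 724584, where input DNA was missing in SPT16-TET/spt6∆202, may mark the partial deletion of SPT6 in that strain, since YGR116W lies on the right arm of chromosome VII. The mean input difference over its 4 probes was −4.21. The run was found by that difference, so the value says nothing on which gene it belongs to, and the explanation stays untested. The run was not compared with an annotation of the same build, and a deletion or substitution of another sequence was not tested.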
